A study of Homo sapiens with 12 samples.

How the data were processed

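RNA was sequenced from Cal27, a cell line from a human squamous carcinoma of the tongue. Cells grew for 5 days in a conditioning phase and for 1 day after replating, on collagen-coated polyacrylamide gels of 0.48 kPa (soft) or 20 kPa (stiff). The labels give 4 conditions with 3 libraries each. The soft-to-soft cells stayed on soft gels. The stiff-to-soft cells were conditioned on stiff gels and replated on soft ones. The LPA-to-soft cells were conditioned on soft gels with lysophosphatidic acid (LPA) and replated on soft gels without it. The LPA-to-FAKi cells had the same conditioning and were replated on soft gels with an inhibitor of focal adhesion kinase (FAK). The series design puts the stiff-to-soft and LPA-to-soft conditions in a class that had learned, and the other 2 conditions in a class that had not. Per the labels, RNA was isolated with an RNeasy kit and libraries were made with a stranded TruSeq kit. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

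The authors deposited a table of whole-number read counts per gene symbol and a table of normalized values on a log2 scale. The submitters' processing notes name cutadapt, FastQC, STAR, HTSeq and DESeq2 without versions, and the genome build hg19. The order and settings of those steps, the strand setting of the counting and the gene annotation are not given in the sources used here. The deposited log2 values were found to be log2 of the count times a factor per library, plus 1. The factor was constant over genes to a relative range of 6.9e-09, and its product with a median-ratio size factor lay between 0.841 and 0.851. The log2 table therefore held no information beyond the deposited counts and entered no test.

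The count table held 25382 symbols, of which 5880 had no count in any library. Symbols that a spreadsheet had turned into dates numbered 28 and held 0.1781% of the counts, and 2 symbols stood on 4 lines in all. No column was left without a sample, and 0 pairs of libraries held identical values. Total counts ran from 62953957 to 122311183 per library. Low counts differed in kind between libraries. Of counts from 1 to 19, between 96.8% and 97.8% were even in 10 libraries, against 42.9% and 42.2% in soft-to-soft replicates 1 and 2. The low counts of these 2 libraries thus followed another rule than those of the other 10. A constant factor on counts is removed by library scaling, but a difference in which reads were counted is not. Results against soft-to-soft were therefore also computed without these libraries and with the counts of the other 10 halved.

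Genes were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F test on the deposited counts, with TMM scaling and the low-count filter of edgeR by the 4 conditions, which left 15437 genes. A gene is called where its Benjamini-Hochberg adjusted p is under 0.05. Learned against not learned was fitted as a model of 2 classes with 6 libraries each, and every comparison of 2 conditions as a contrast in a model of the 4 conditions over all 12 libraries, which share an estimate of the spread. The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The fit without replicate number is the main one, and a fit with replicate number as a block was planned beside it.

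The numbers were then checked for pairing. After the mean of each condition was taken off, libraries with the same number correlated with r from 0.312 to 0.659 over 18 pairs (median 0.478). Libraries with different numbers correlated with r from -0.517 to 0.037 over 36 pairs, and 12 of 12 libraries correlated best with another library of their own number. The replicate numbers come from the sample labels, which do not say what a number stands for. By the threshold of 0.1 the numbers pair the samples, and values from the fit with the block are given for genes, and for the lists described here, where it changes a call. In all sums of squares over genes, replicate number held 47.2% and condition 22.5%.

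Levels are CPM with TMM scaling, given as mean ± SD, and fold changes are edgeR log2 fold changes ± SE. Log2 CPM values used a prior count of 2. Gene lists, 29 in all, were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with adjustment over the lists within a comparison. Each camera call was tested again with a correlation estimated from the data and with fry, also of limma. The lists covered YAP/TAZ targets, SRF/MRTF targets, focal adhesion, extracellular matrix, matrix proteases, partial epithelial-mesenchymal transition of head and neck carcinoma, mesenchymal factors, epithelial junctions, keratinocyte differentiation, basal keratinocyte genes, interferon response, NF-kB and cytokine response, immediate early genes, TGF-beta targets, S phase, G2 and M phase, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, the integrated stress and unfolded protein response, NRF2 targets, LPA receptors and metabolism, ribosomal proteins, mitochondrially encoded genes and nuclear genes of oxidative phosphorylation. A further 3 lists held markers of fibroblasts, leukocytes and endothelial cells. The results of 1 other list are not reported here.

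The rule for named genes took, per comparison, the called genes with the largest rise and fall among those with a mean log2 CPM of at least 1 whose groups did not overlap (for the classes, whose condition means lay on the right sides). It took up to 12 each way for the classes, 10 for stiff-to-soft and LPA-to-soft against soft-to-soft and for LPA-to-FAKi against LPA-to-soft, and 5 for the other 2 comparisons. Where no gene was called it took the 3 smallest p-values each way, as values. From each list it took up to 4 called members, or the 2 with the smallest p as values. PTK2, the gene of FAK, and the LPA receptors were named in any case. No gene was called without the block, so the rule was applied also to the fit with the block, a choice made after the data were seen. THBD and the genes of the 4-condition contrast with the block fall outside the rule and were chosen after their values were seen.

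Other settings planned beside it were the replicate block, DESeq2 1.42.0 (Wald test, its own filter), limma voom, size factors of the DESeq2 kind (RLE), no low-count filter, a mean log2 CPM of at least 1, robust estimation of the spread, an adjusted p under 0.01, a log2 fold change of at least 1, a 4-condition model for the classes, a fit of only the 2 conditions compared, classes without 1 of the conditions, voom with condition as a random block, and leaving out each library in turn. Chosen after the data were seen were these alternatives together with the block, the halved counts, the fits without soft-to-soft replicates 1 and 2, and a correction for transcript length and GC content by a loess trend per library (span 0.5) in the fit with the block. Comparisons that share control libraries were set beside 20 simulations of unchanged groups.

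The tests were tried on simulated counts with 67, 67 and 66 genes changed 1.5, 2 and 4-fold. For the classes, 15253 simulated genes were tested, and the fit without the block recovered 67.2%, 89.6% and 97% of the changed genes. With the block it recovered 94%, 98.5% and 100%, with 8 other genes called. For stiff-to-soft against soft-to-soft, 15246 genes were tested, and recovery was 20.9%, 74.6% and 90.9% without the block. With the block it was 80.6%, 92.5% and 100%, with 9 other genes called. Camera recovered a lowered list of immediate early genes in a simulated stiff-to-soft comparison and called 0 of the other lists. Simulated counts keep no correlation between genes, so list tests on real counts have less certain error rates. For the same reason simulated ranges of a correlation or covariance over genes may be too narrow.

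Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Transcript length and GC content came from the GRCh38 annotation by gene symbol, with a value for 94.5% of the genes used in that check. Coordinates are not given, because the counts use hg19 and the annotation used here is on another build. Genes with near-identical copies (small proline-rich proteins, late cornified envelope proteins, type I and II keratins, aldo-keto reductases) can share reads, and their values are less certain.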

Results

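Cal27 cells were conditioned for 5 days and replated for 1 day, and the study asks what the cells keep of their conditioning (mechanical memory) and how contractility bears on it. LPA is a lipid that acts through G protein-coupled receptors, and FAK is a kinase of integrin adhesions. Expression was measured by RNA sequencing in 12 libraries, 3 for each of the soft-to-soft, stiff-to-soft, LPA-to-soft and LPA-to-FAKi conditions. Total counts in replicates 1, 2 and 3 were 73018393, 62953957 and 119741813 for soft-to-soft, 106237675, 101311628 and 107075060 for stiff-to-soft, 107080066, 101153180 and 121070917 for LPA-to-soft, and 76083175, 122311183 and 83122251 for LPA-to-FAKi. Between 16259 and 17464 symbols had a count in a library. Mitochondrial genes took 4.31% to 8.22% of the counts and the 10 most abundant genes took 5.96% to 9.24%.

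The largest differences between libraries followed replicate number and not condition. The first principal component held 31.9% of the variance and the second 22.8%. Mean log2 CPM of the keratinocyte differentiation list was 4.35 to 4.91 in the libraries numbered 1 and 2.63 to 3.08 in those numbered 3. The interferon response list ran the other way, at 5.21 to 6.05 in the libraries numbered 1 and 6.30 to 7.08 in those numbered 3. Each comparison below is given without replicate number, as planned, and with it as a block where that changed the outcome.

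**Figure D1:**
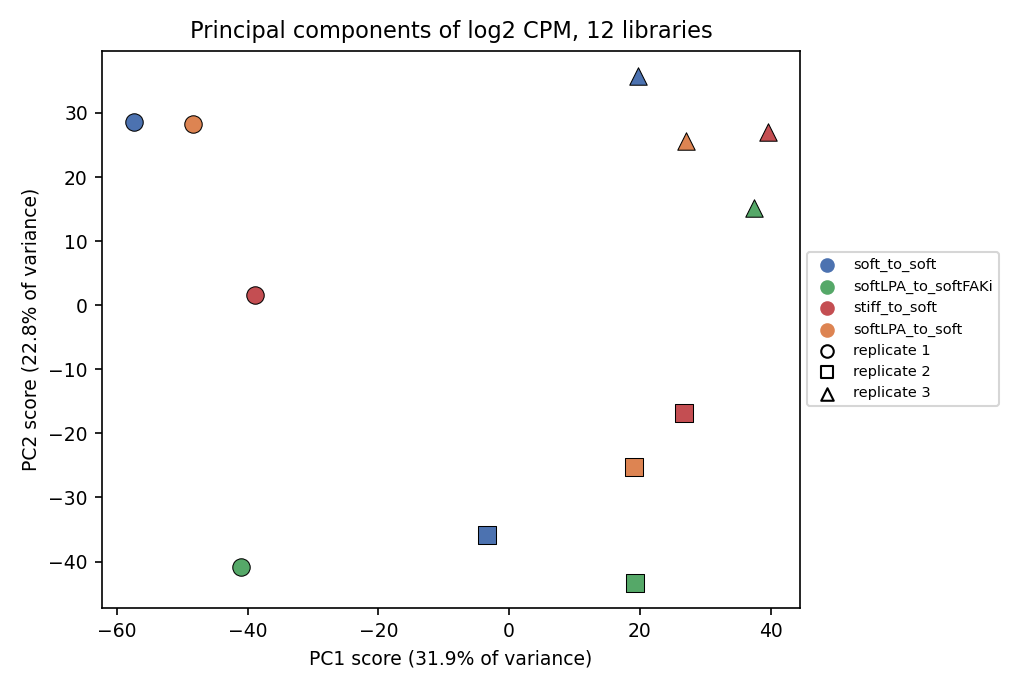
Scores of the 12 libraries on the first (x axis, 31.9% of variance) and second (y axis, 22.8%) principal components of log2 CPM, coloured by condition, with a marker shape for each replicate number. Libraries numbered 1 have the lowest scores on the first component, and those numbered 2 lie below those numbered 3 on the second. LPA-to-FAKi replicate 1 lies apart from the other libraries of its number on the second.

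The classes were compared to ask which genes mark cells that had learned. Fibronectin (FN1), a matrix glycoprotein that integrins bind, was higher in the learned class at 152.6 ± 62.3 CPM than in the other class at 90.2 ± 42.8 CPM (SD, n = 6). With the replicate block it rose by 0.80 ± 0.095 on the log2 scale (edgeR quasi-likelihood test, adjusted p = 0.0259), and by 0.87, 0.87 and 0.63 within replicate numbers 1, 2 and 3. No other gene passed in the edgeR fit with the block. FN1 was not called in voom with condition as a random block and no replicate block, where it stood at 0.79 with an adjusted p of 0.71. Since edgeR without the replicate block did not call FN1 either, this fit does not show the weight of the spread between conditions. A contrast of the 4 conditions with the block called 7 genes, chosen after their values were seen. FN1 at 0.79 and TNS3, a focal adhesion protein, at 0.36 were higher. The thrombomodulin gene THBD at -0.39, the EGF receptor ligands EREG at -0.39 and HBEGF at -0.38, and the squamous genes SPRR2A at -0.81 and TMPRSS11D at -0.70 were lower, with adjusted p from 0.00387 to 0.0398. This contrast does not count the spread between the conditions of a class as error. THBD did not mark both learned conditions, with means of 65.8 CPM in stiff-to-soft and 91.0 CPM in LPA-to-soft. Its means were 91.7 CPM in soft-to-soft and 112.1 CPM in LPA-to-FAKi.

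Without the block edgeR called 0 of 15437 genes between the classes, FN1 included (0.76 ± 0.329, adjusted p = 1). At an unadjusted p under 0.05 it had 446 genes, and DESeq2 and limma voom also called 0. If all libraries were exchangeable 772 such genes would be found, but replicate numbers make that untrue. Among 100 drawn splits without the block, the real one included, 47 had at least 446 such genes. Many of these splits do not divide each replicate number evenly, so this share is no full measure of chance. The genes with the smallest p are given as values. The muscle kinase ALPK3 stood at 0.75 ± 0.155, the actin-binding SVIL at 0.32 ± 0.066 and the phosphodiesterase PDE8A at 0.33 ± 0.077. On the other side EEPD1 stood at -0.32 ± 0.079, PHLDA2 at -0.49 ± 0.121 and DEGS2, below 0.2 CPM in both classes, at -1.98 ± 0.495. With the block edgeR had 1535 genes at an unadjusted p under 0.05, voom called 1 and DESeq2 called 130, of which 70 rose and 60 fell. Of 100 drawn splits with 2 libraries of each replicate number per class, the real one included, 8 had at least 1535 such genes. The highest other split had 3296. The edgeR count with the block was 4 without soft-to-soft replicate 1. It was 1 without LPA-to-FAKi replicate 3, LPA-to-soft replicate 2 or LPA-to-soft replicate 3, and 0 without any of the other 8 libraries, so FN1 was called in 4 of these 12 fits (adjusted p from 0.00575 to 0.155). After a correction for transcript length and GC content FN1 stood at 0.73 with an adjusted p of 0.137.

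Differentiation and basal keratinocyte genes were lower in the learned class. Of 47 keratinocyte differentiation genes, 38 had negative fold changes (median -0.42, camera adjusted p = 7.81e-04, and 0.876 as the adjusted p with an estimated correlation). With the block 0 of them were called over all genes and 14 fell when adjusted over the list alone. LCE3D and LCE3E, late cornified envelope genes with near-identical copies, stood at -4.99 and -4.82 without being called. Of 25 basal keratinocyte genes, 21 had negative values (median -0.19, adjusted p = 0.00721, and adjusted p = 0.79 with an estimated correlation), and 5 fell adjusted over the list alone with the block. KRT6B stood at -0.78. Immediate early genes, which respond to growth factors within minutes, had 35 of 37 members below 0 (median -0.24, adjusted p = 2.57e-05, and adjusted p = 0.79 with an estimated correlation). With the block 6 of them fell adjusted over the list alone. Their mean log2 CPM in replicates 1, 2 and 3 was 6, 5.49 and 6.24 in stiff-to-soft and 6.53, 5.6 and 6.45 in LPA-to-soft. It was 6.23, 5.68 and 6.46 in LPA-to-FAKi and 6.59, 5.95 and 6.71 in soft-to-soft. Within each replicate number stiff-to-soft was lowest and soft-to-soft highest, so the class difference rests on both of these conditions. AREG and EREG, again EGF receptor ligands, stood at -0.69 and -0.38.

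Extracellular matrix genes lay slightly higher in the learned class. Of 36 such genes 24 were positive (median 0.11, camera adjusted p = 0.00552, and adjusted p = 0.79 with an estimated correlation), with FN1 called by the block. In stiff-to-soft against soft-to-soft the median was lower, at 0.05 (20 of 36 positive, camera adjusted p = 0.0735). MYH9 at 0.15 and MYH10 at 0.17, the heavy chains of non-muscle myosin II, were not called. NF-kB and cytokine genes (27 of 35 positive, median 0.14, adjusted p = 7.81e-04), hypoxia and glycolysis (30 of 36, 0.11, adjusted p = 0.00721), G2 and M phase (26 of 34, 0.06, adjusted p = 0.00474) and cholesterol synthesis (21 of 25, 0.12, adjusted p = 0.0397) were higher. S phase (30 of 34 negative, -0.11, adjusted p = 0.00138) and mitochondrially encoded genes (13 of 13 negative, -0.17, adjusted p = 0.012) were lower. With an estimated correlation the adjusted p of these 6 lists lay between 0.79 and 0.879. The hypoxia difference includes LPA-to-soft replicate 1, which stood apart on this list (mean log2 CPM 6.71, against 5.87 to 6.12 in the other learned libraries). For stiff-to-soft against LPA-to-soft, without the block, the S phase median was 0.096 and the hypoxia median -0.137. These are close in size to the class medians and opposite in sign, so both class differences rest mainly on LPA-to-soft. G2 and M phase had medians of -0.02 and -0.08 in the learned conditions and -0.22 in LPA-to-FAKi, each against soft-to-soft, so its class difference rests on LPA-to-FAKi. The mitochondrially encoded call was lost with the block and without soft-to-soft replicates 1 and 2 (adjusted p = 0.0569). BIRC3 stood at 0.40, CENPF at 0.30 and MKI67 at 0.29, none called.

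The lists closest to the mechanical question did not pass. YAP/TAZ targets had a median of 0.01 (12 positive and 10 negative, adjusted p = 0.6), SRF/MRTF targets -0.02 (9 and 13, adjusted p = 0.956) and focal adhesion genes 0.04 (20 and 18, adjusted p = 0.293). In no comparison of this study did camera without the block call these 3 lists. PTPN14, a YAP target, stood at 0.29, and the adhesion genes ITGAV and LPP at 0.34 and 0.40. PTK2 stood at 0.11 ± 0.063, with 52.1 ± 2.28 CPM in the learned class and 48.4 ± 4.11 CPM in the other. Medians of the other lists that did not pass without the block were -0.18 for matrix proteases (adjusted p = 0.47), -0.04 for partial epithelial-mesenchymal transition (0.956), 0.02 for mesenchymal factors (0.956), -0.04 for junctions (0.519), -0.02 for TGF-beta targets (0.956), 0.04 for fatty acid synthesis (0.183), 0.06 for the stress response (0.199), -0.10 for NRF2 targets (0.0567), -0.01 for LPA receptors (0.956), -0.001 for ribosomal proteins (0.637) and -0.02 for oxidative phosphorylation (0.34). For the SRF/MRTF, partial transition, TGF-beta and LPA receptor lists camera's direction was up although the medians lay below 0. The interferon list had a median of 0.05 (33 of 45 positive, adjusted p = 0.0638), and passed with the block (adjusted p = 0.0126, and adjusted p = 0.77 with the block and an estimated correlation). Its median was below 0 in both learned conditions against soft-to-soft (-0.33 and -0.10), so the class value rests on the lower LPA-to-FAKi libraries (-0.58). Fatty acid synthesis also passed with the block (adjusted p = 0.0389, and adjusted p = 0.63 with the block and an estimated correlation), and not without soft-to-soft replicates 1 and 2 (0.382). Markers of other cell types did not pass either, with medians of 0.16 for fibroblasts (adjusted p = 0.135), -0.09 for leukocytes (0.956) and 0.32 for endothelium (0.293), where CDH5 stood at 0.70 and CD68 at -0.69.

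Stiff-to-soft was compared with soft-to-soft to ask what remained of stiff conditioning after a day on soft gels. CSF2, which encodes the cytokine GM-CSF, was at 41.6 ± 23.2 CPM against 15.9 ± 6.55 CPM (SD, n = 3) and rose by 1.32 ± 0.126 with the replicate block (edgeR adjusted p = 0.00384). FN1 was at 170.2 ± 78.7 against 83.6 ± 37.5 CPM and also rose (adjusted p = 0.00384). The basal keratins fell: KRT14 by 1.68 ± 0.322, KRT17 by 0.75 ± 0.111 and KRT15 by 0.73 ± 0.073 (adjusted p = 0.048, 0.0185 and 0.00384). The collagenase MMP1 fell by 1.27 and the stromelysin MMP10 by 1.52 (adjusted p = 0.0134 and 0.012). In all, 37 genes rose and 53 fell with the block, and each of the 90 moved the same way in 3 of 3 replicate pairs. The fit with the block favours genes that move alike in these pairs, so this is no separate support.

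Among the genes that rose were the simple epithelial keratin KRT7 (0.81 ± 0.145, adjusted p = 0.0402), the complement gene C2 (0.75 ± 0.138, adjusted p = 0.0424), xanthine dehydrogenase XDH (0.62 ± 0.102, adjusted p = 0.0286), KIAA1244 (0.48, adjusted p = 0.0449) and the glycosyltransferase MGAT5 (0.42, adjusted p = 0.025). The axon guidance receptor ROBO3 rose by 1.53 from 0.464 CPM (adjusted p = 0.0474). L1CAM, a neural adhesion molecule, stood at 1.30 ± 0.255 just past the threshold (adjusted p = 0.0531). The receptor phosphatase PTPRZ1 fell by 1.60, the stem cell factor SOX2 by 1.14 (21.8 ± 9.28 against 45.8 ± 13.7 CPM), SOWAHC by 0.72, the KIT ligand KITLG by 0.63 and EREG by 0.48, with adjusted p from 0.012 to 0.0471. IER3, STK17B, MCL1 and ABHD17C fell by 0.47, 0.41, 0.34 and 0.34. MCL1 and IER3 are known as survival genes.

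Immediate early genes were lower in all 3 pairs. Of 37, 35 had negative fold changes without the block (median -0.45, camera adjusted p = 6.4e-11, and adjusted p = 0.969 with an estimated correlation), and the pair medians were -0.53, -0.39 and -0.42. With the block 10 fell over all genes and 22 adjusted over the list alone, and fry also passed (adjusted p = 0.0173). The transcription factors EGR1, EGR3, NR4A2 and NR4A3 fell by 0.72, 1.32, 0.85 and 2.29, with adjusted p from 0.0358 to 0.0471. KLF10, also a TGF-beta target, fell by 0.53.

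Squamous genes fell in the same comparison. Of 47 differentiation genes 41 were negative (median -0.65, adjusted p = 1.52e-05, and adjusted p = 0.969 with an estimated correlation). With the block 5 fell over all genes and 18 adjusted over the list alone, and fry passed (adjusted p = 0.0246). Camera with the block and an estimated correlation did not (adjusted p = 0.123). KRT13, a keratin of non-cornified oral epithelium, fell by 1.41, SPRR2E by 1.23, TMPRSS11D by 1.22 and SPRR2A by 1.03, with adjusted p from 0.00547 to 0.0418. SPRR2A, SPRR2E, KRT14 and KRT17 have near-identical copies that can share reads. Of 25 basal genes 23 were negative (median -0.33, adjusted p = 2.29e-05, and adjusted p = 0.969 with an estimated correlation), with 4 called by the block and 10 adjusted over the list alone. The desmosome genes PKP1, DSG3 and PERP fell by 1.10, 0.66 and 0.32 among 33 junction genes, of which 4 rose and 9 fell adjusted over the list alone. The transcription factor SNAI2 fell by 0.67 (adjusted p = 0.012).

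Other lists were called without the block and lost with an estimated correlation, where each had an adjusted p of 0.969. The interferon list was lower (39 of 45 negative, median -0.33, adjusted p = 0.0185), with pair medians of -0.19, 0.05 and -0.59. IFI6 fell by 1.16 as the 1 member called with the block, and 7 fell adjusted over the list alone. NF-kB and cytokine genes were higher (22 of 35, 0.10, adjusted p = 0.0131), with pair medians of -0.20, 0.86 and 0.09, and were not called with the block and without soft-to-soft replicates 1 and 2 (adjusted p = 0.249). With the block CSF2 and CSF1 (0.68 ± 0.125, adjusted p = 0.0426) rose and IER3 fell. Ribosomal protein genes were higher in 64 of 65 cases (median 0.09, adjusted p = 2.05e-04), and 13 of 13 mitochondrially encoded genes were lower (-0.20, adjusted p = 0.0264). The mitochondrial share of counts in replicates 1, 2 and 3 was 5.54%, 4.33% and 8.04%, against 8.01%, 4.4% and 8.22% in soft-to-soft. The mitochondrial shift thus came mostly from replicate 1. PPP1R15A, of the stress response, fell by 0.48 with the block. Extracellular matrix (median 0.05, adjusted p = 0.0735 without and 0.046 with the block) and junction genes (-0.08, 0.663 and 0.0369) passed only with the block, and not with an estimated correlation (adjusted p = 0.767 and 0.722). The first was lost with the correction for length and GC content (0.0807) and the second without soft-to-soft replicates 1 and 2 (0.238).

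Without the block edgeR and voom called 0 genes here, and DESeq2 called 3, C2, L1CAM and ROBO3, all higher. In edgeR 300 genes had an unadjusted p under 0.05, against 772 if all libraries were exchangeable, which replicate numbers make untrue. With the block voom called 119 and DESeq2 506, among them 83 and 90 of the 90. Soft-to-soft replicates 1 and 2, whose low counts followed another rule, are 2 of the 3 controls. Without them 1 control library is left. The median absolute log2 fold change of the 90 genes was then 0.639, against 0.69 with all libraries. The 90 genes were chosen with these controls included, so this size does not show that the calls hold without them. Without a library the count was 44, 41 and 11 (soft-to-soft 1, 2 and 3), 228 and 35 (LPA-to-FAKi 1 and 2), 13 and 7 (stiff-to-soft 2 and 3) and 44 and 31 (LPA-to-soft 2 and 3). All 90 genes kept their direction in these fits, but they were chosen in the same libraries and moved alike in every pair. A turn was therefore unlikely from the start, and the kept direction is no separate support for the calls.

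**Figure D2:**
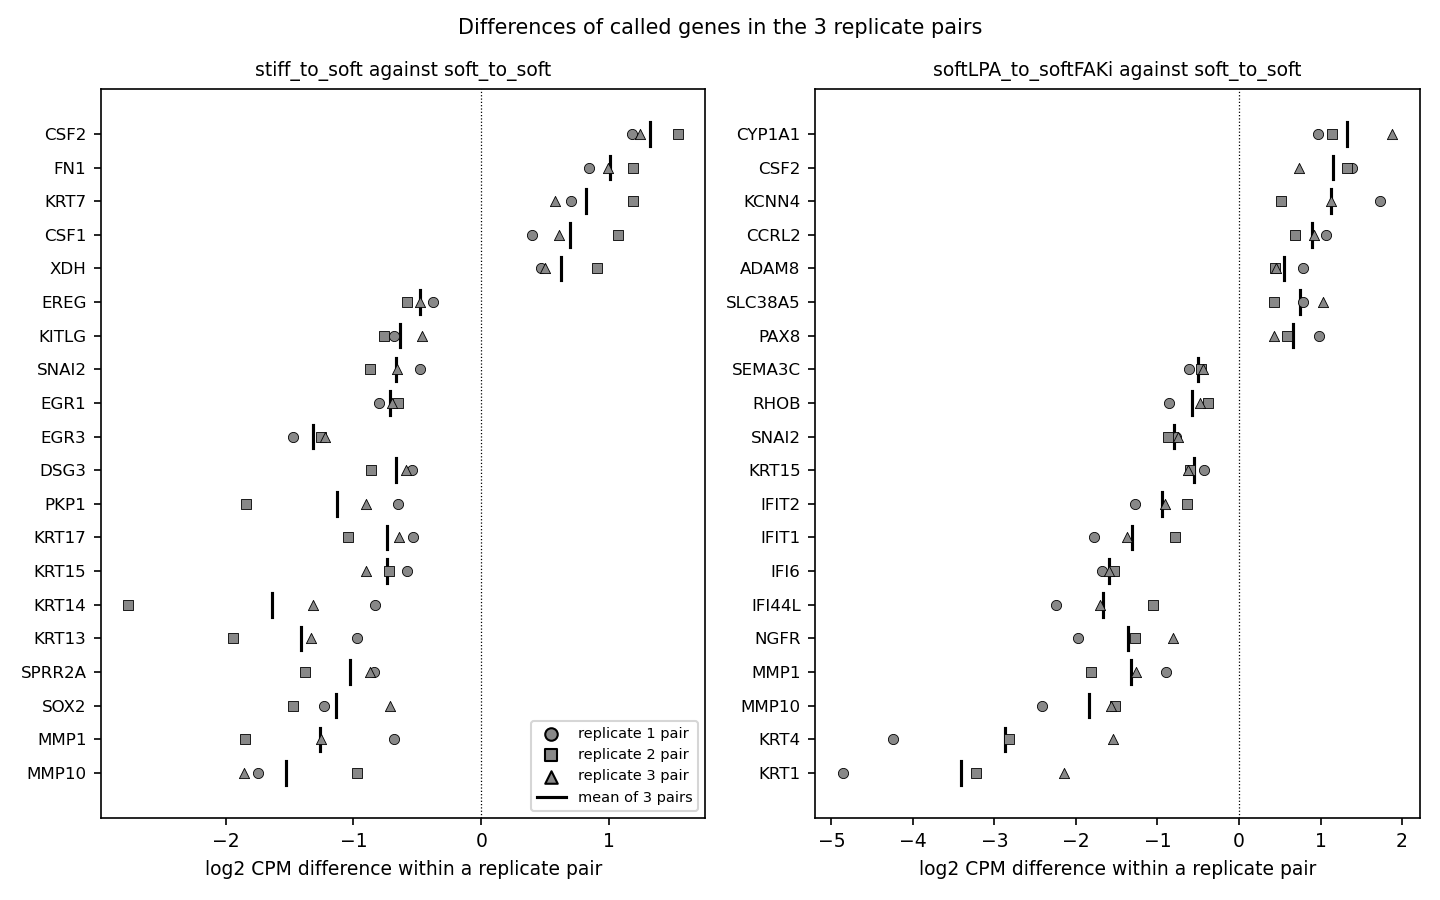
Log2 CPM difference within each replicate pair (x axis) for called genes (y axis), stiff-to-soft against soft-to-soft on the left and LPA-to-FAKi against soft-to-soft on the right; marker shapes give the pair and bars the mean of 3 pairs. All 3 pairs lie on the same side of 0 for each gene drawn, which the choice of genes by the fit with the block favours.

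LPA-to-soft was compared with soft-to-soft to ask what remained of LPA conditioning. No gene passed in edgeR, with or without the block. The largest shifts by p were in the sorting nexin SNX30 (33.2 ± 1.16 against 23.7 ± 2.14 CPM, 0.48 ± 0.091 on the log2 scale), the transcription factor BBX (0.31) and the sodium-proton exchanger SLC9A7 (0.38). FN1 stood at 0.72 ± 0.103, LPP at 0.64 ± 0.096 and MMP1 at -1.17 ± 0.173 in the fit with the block, each with an adjusted p of 0.151, the smallest reached. WHAMMP2, NRN1L and PAX5 stood at -2.11, -3.35 and -1.83, all below 0.3 CPM. Without the block edgeR had 211 genes at an unadjusted p under 0.05, with 0 called by edgeR, DESeq2 and voom. The value of 772 for exchangeable libraries does not hold here either, since replicate numbers pair them. With the block the count at p under 0.05 was 1231, voom called 0 and DESeq2 called 148, of which 91 rose and 57 fell.

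The lists moved in LPA-to-soft cells as small shifts of many members. Differentiation genes (39 of 47 negative, median -0.34, adjusted p = 0.00969), basal genes (24 of 25, -0.25, adjusted p = 0.00969), immediate early genes (33 of 37, -0.20, adjusted p = 0.00614), S phase genes (33 of 34, -0.11, adjusted p = 0.00507) and mitochondrially encoded genes (13 of 13, -0.36, adjusted p = 0.00151) were lower. Hypoxia and glycolysis (30 of 36 positive, 0.12, adjusted p = 0.00614), NF-kB genes (23 of 35, 0.05, adjusted p = 0.0323) and fatty acid synthesis (15 of 17, 0.11, adjusted p = 0.0493) were higher. With an estimated correlation each of these 8 lists had an adjusted p of 0.86. With the block and without soft-to-soft replicates 1 and 2 the basal (adjusted p = 0.123), NF-kB (0.553) and hypoxia (0.0944) calls were lost. The hypoxia shift came from replicate 1, with pair medians of 0.36, 0.02 and -0.04. KRT10 stood at -0.53, KRT4 at -1.36, AREG at -0.54, GPX2 at -0.70, PTPN14 at 0.42, ACACA at 0.33 and HK2 at 0.28, none called. Adjusted over the list alone with the block, 5 basal and 3 differentiation genes fell. Oxidative phosphorylation (median -0.05, adjusted p = 0.053 without and 0.00238 with the block) passed only with the block, and not with an estimated correlation (adjusted p = 0.855). It was lost with the correction for length and GC content (0.191), which fold changes followed here (Spearman 0.372 with length), and without soft-to-soft replicates 1 and 2 (0.283).

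Stiff and LPA conditioning were set side by side to ask whether they left the same trace. Their fold changes against soft-to-soft correlated across genes at r = 0.494, and 65.4% had the same sign. Unchanged simulated groups against the same controls gave r from 0.481 to 0.562, with a mean of 0.518. Simulated genes vary independently, so this range may be too narrow. The covariance was 0.0722 against a simulated 0.0593, a difference of 0.0128. Among genes with a mean log2 CPM of at least 1, r was 0.596 against 0.506 in simulations. When the fold changes came from different replicate numbers, r had a median of 0.07 (0.013 to 0.153). DESeq2 with the block called 34 genes up and 29 down in both, where independent lists would share 1.09 and 0.856. The controls are too few to split with 2 libraries in each part, and part of the excess may come from the shared controls. Genes whose 6 learned libraries all lay above or all below the 6 others numbered 21 (15 above), against 33.4 (0.216% of the genes) if all 12 libraries were exchangeable. Replicate numbers pair the libraries, so that value is not the one for these data.

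LPA-to-FAKi was compared with LPA-to-soft to ask what FAK inhibition after replating changed. Interferon response genes were lower, with 44 of 45 negative and a median of -0.52 (camera adjusted p = 5.05e-05, and adjusted p = 0.921 with an estimated correlation). The pair medians were -0.61, -0.13 and -0.64, and with the block 28 members fell adjusted over the list alone. The antiviral genes RSAD2 and PARP14 stood at -1.04 and -0.58. NRF2 targets were higher (21 of 27 positive, median 0.23, adjusted p = 0.0081, and adjusted p = 0.921 with an estimated correlation), and 13 rose and 1 fell adjusted over the list alone with the block. AKR1C1, which has near-identical copies, stood at 2.15.

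No single gene passed in edgeR in this comparison, with or without the block. By p the first were the proton pump subunit ATP6V0B (184.0 ± 10.4 against 138.3 ± 6.61 CPM, n = 3, 0.41 ± 0.09), the lysosomal transporter SPNS1 (0.38), B3GNT3 (0.59), HOOK1 (-0.40), MSRB3 (-0.81) and ZC3H6 (-0.88). The lysosomal protein CD68 was at 28.8 ± 13.5 against 12.7 ± 3.77 CPM (1.18 ± 0.34). With the block the adjusted p of all of these was 0.0752, the smallest reached. The nerve growth factor receptor NGFR stood at -1.14, RHOC at 0.47, ARHGEF12 at -0.33, FOSL1 at 0.77, AREG at 0.80, CCNE1 at 0.46, ITGAV at -0.38 and PTPN14 at -0.40. PTK2, which encodes the inhibited kinase, was at 47.1 ± 2.74 against 51.4 ± 2.26 CPM (-0.13 ± 0.094), lower in 3 of 3 pairs and not called.

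Cell cycle lists moved apart under FAK inhibition. S phase genes were higher (30 of 34, 0.18, adjusted p = 3.93e-04) and G2 and M phase genes lower (29 of 34, -0.15, adjusted p = 9.7e-05), with CENPF at -0.48. The pair medians were 0.35, 0.13 and 0.05 for S phase, and -0.44, 0.01 and -0.06 for G2 and M phase. Hypoxia and glycolysis was lower (29 of 36, -0.16, adjusted p = 0.00247) and ribosomal proteins higher (61 of 65, 0.10, adjusted p = 3.93e-04). The pair medians were -0.58, -0.07 and 0.09 for hypoxia and glycolysis, whose shift came mostly from replicate 1, and 0.14, -0.01 and 0.16 for ribosomal proteins. With an estimated correlation these 4 lists had an adjusted p of 0.921. Passing only with the block, and not with an estimated correlation, were NF-kB and cytokine genes (median -0.28, adjusted p = 0.0849 without and 0.0491 with the block), cholesterol synthesis (-0.21, 0.117 and 0.0203) and oxidative phosphorylation (0.05, 0.184 and 0.0472), each with an adjusted p of 0.915 with the block and an estimated correlation. Oxidative phosphorylation was lost with the correction for length and GC content (adjusted p = 0.605) and without soft-to-soft replicates 1 and 2 (0.0903).

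Of single genes edgeR, DESeq2 and voom called 0 without the block in this comparison, with 838 at an unadjusted p under 0.05 in edgeR. With the block edgeR called 0 with 3439 at p under 0.05, voom called 37 and DESeq2 1224, of which 637 rose and 587 fell. The edgeR count with the block was 639 without soft-to-soft replicate 2, 62 without LPA-to-FAKi replicate 3 and 1 without LPA-to-FAKi replicate 2 or LPA-to-soft replicate 2. Reversal of LPA effects by FAK inhibition could not be counted in edgeR, with or without the block, or in DESeq2 without it, since these fits called 0 genes in both steps. DESeq2 with the block gave 14 genes up with LPA and down with the inhibitor, and 2 the other way, where independent lists share 4.09 and 2.78. LPA-to-soft is part of both steps, and part of the excess of the 14 may come from these shared libraries. The fold changes of both steps correlated at r = -0.32, against -0.519 to -0.439 in simulated unchanged groups. The covariance of -0.0571 lay within the simulated -0.0637 to -0.0478. Simulated genes vary independently, so these ranges may be too narrow to judge the real values by.

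LPA-to-FAKi was also compared with soft-to-soft, to ask how far LPA conditioning with the inhibitor differed from no conditioning. CSF2 rose by 1.16 ± 0.126 with the block (36.8 ± 19.5 against 15.9 ± 6.55 CPM, SD, n = 3, edgeR adjusted p = 0.0111). The keratins of stratified epithelium KRT1 and KRT4 fell by 3.38 and 2.75 (adjusted p = 0.0251 and 0.0383), while their list was evenly spread (23 of 47 positive, median -0.06, camera adjusted p = 0.324). KRT1 was at 2.74 ± 1.16 against 47.2 ± 58.1 CPM. SNAI2, MMP10 and MMP1 fell by 0.80, 1.83 and 1.34 (adjusted p = 0.0111, 0.0111 and 0.0192). In all 24 genes rose and 63 fell with the block, each in 3 of 3 pairs, which the choice of genes by that fit favours.

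The dioxin-induced cytochrome CYP1A1 (1.35, adjusted p = 0.0456), the potassium channel KCNN4 (1.14, adjusted p = 0.0253), CCRL2 (0.91), the amino acid transporter SLC38A5 (0.74), PAX8 (0.67) and the protease ADAM8 (0.56) rose. DHRS2 and CYP4B1, both below 2 CPM, fell by 3.43 and 2.86. AKR1B10 fell by 1.82, PTPRZ1 by 1.61, NGFR by 1.30, MSRB3 by 0.92, DSC3 by 0.59, RHOB by 0.57, KRT15 by 0.55 and the semaphorin SEMA3C by 0.51. The adjusted p of these genes lay between 0.0192 and 0.0468. SLC26A9 stood at 2.34 and was not called (adjusted p = 0.0845 with the block).

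Among the lists called without the block interferon response genes fell most (43 of 45 negative, median -0.58, adjusted p = 3.41e-07, and adjusted p = 0.885 with an estimated correlation). With the block 8 fell over all genes and 35 adjusted over the list alone. IFI44L fell by 1.63, IFI6 by 1.59, IFIT1 by 1.27 and IFIT2 by 0.92, and the pair medians were -0.75, -0.02 and -0.76. G2 and M phase genes were lower in 34 of 34 cases (-0.22, adjusted p = 2.15e-10) and ribosomal proteins higher in 65 of 65 (0.11, adjusted p = 2.8e-05). TGF-beta targets (15 of 23 negative, -0.17, adjusted p = 0.0168) and basal genes (18 of 25, -0.09, adjusted p = 0.0304) were lower. With an estimated correlation these 4 lists had an adjusted p of 0.885. With the block and without soft-to-soft replicates 1 and 2, the G2 and M phase (adjusted p = 0.0634), TGF-beta (0.211) and basal (0.613) calls were lost. The G2 and M phase pair medians were -0.53, -0.12 and -0.02. Immediate early genes passed only with the block (27 of 37 negative, adjusted p = 0.186 without and 0.00122 with it, and adjusted p = 0.762 with the block and an estimated correlation), and EGR3 and NR4A3 fell by 1.46 and 2.39. NRF2 targets passed only with the block as well (median 0.08, adjusted p = 0.189 without and 0.0219 with it, and 0.762 with the block and an estimated correlation), and not without soft-to-soft replicates 1 and 2 (0.0634). Fibroblast markers, of another cell type, had a median of -1.20 and were not called (adjusted p = 0.319, with all 3 pair medians below 0).

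**Figure D3:**
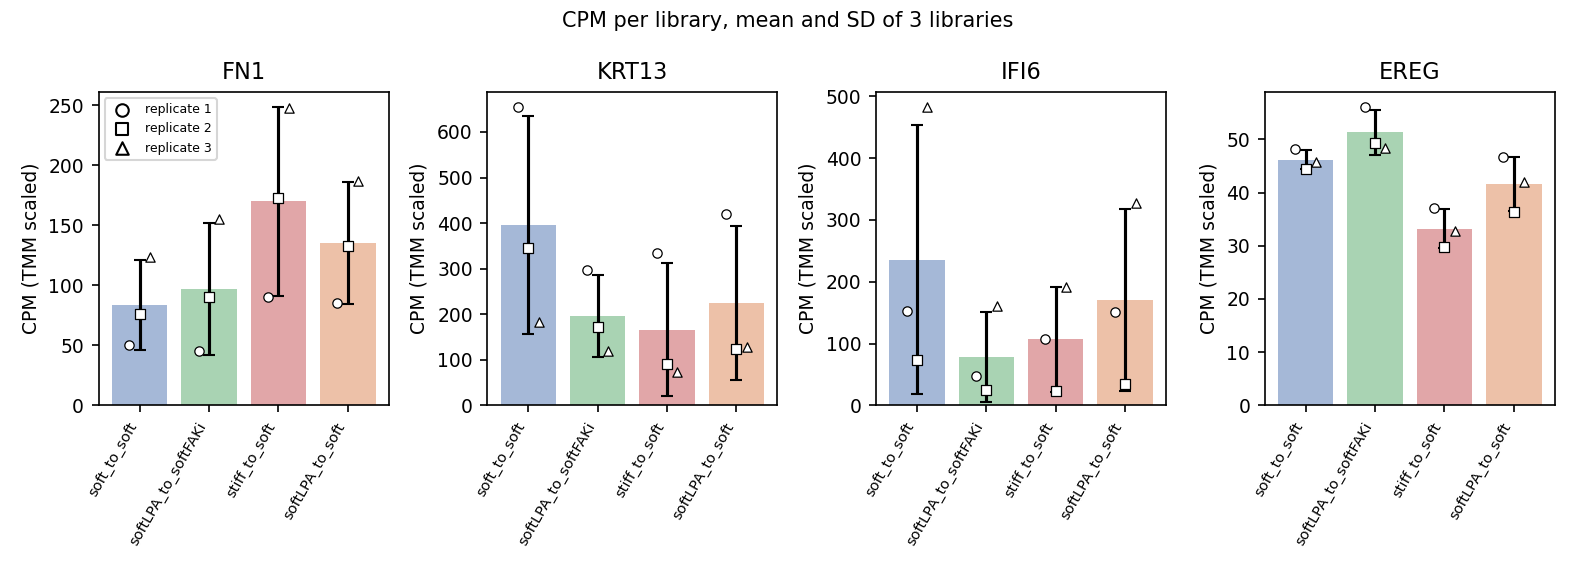
CPM of FN1, KRT13, IFI6 and EREG (y axis, TMM scaled) in the 4 conditions; bars give the mean and error bars the SD of 3 libraries, and marker shapes give the replicate number. FN1 has a mean of 170.2 CPM in stiff-to-soft and 83.6 CPM in soft-to-soft, with the replicate numbers spread within each condition.

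In LPA-to-FAKi against soft-to-soft edgeR and voom called 0 genes without the block, with 548 at an unadjusted p under 0.05 in edgeR, and DESeq2 called 3 lower genes, CYP4B1, DHRS2 and MSRB3. With the block voom called 176 and DESeq2 712, among them 85 and 87 of the 87. Without soft-to-soft replicates 1 and 2 only 1 control library is left. The median absolute log2 fold change of the 87 genes was then 0.838, against 0.773 with all libraries. The 87 genes were chosen with these controls included, so this size does not show that the calls hold without them. Without a library the count was 8, 307 and 0 (soft-to-soft 1, 2 and 3), 13, 28 and 211 (LPA-to-FAKi 1, 2 and 3), 30 (stiff-to-soft 3) and 44 and 49 (LPA-to-soft 2 and 3). All 87 kept their direction in these fits, which is no separate support, since they were chosen in the same libraries and moved alike in every pair. With the block, stiff-to-soft and LPA-to-FAKi shared 6 genes that rose and 15 that fell against soft-to-soft, where independent lists, which leave out the shared controls, share 0.0575 and 0.216. Simulated unchanged groups shared at most 1, but their lists held at most 3 and 2 genes, so neither value is a full measure of chance here. Their fold changes correlated at r = 0.457 against 0.512 in simulations, with a covariance of 0.0965 against 0.0595, and part of the excess may come from the shared controls. CSF2 and FN1 differ here: CSF2 rose in both, whereas FN1 was called in stiff-to-soft and not in LPA-to-FAKi, a difference that was not tested.

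Stiff-to-soft and LPA-to-soft, the 2 learned conditions, were compared directly. THBD, an anticoagulant gene chosen after its values were seen, was lower after stiff conditioning (65.8 ± 12.6 against 91.0 ± 20.6 CPM, SD, n = 3). It fell by 0.46 with the block (edgeR adjusted p = 0.0496), and by 0.49, 0.53 and 0.36 in pairs 1, 2 and 3. No other gene passed in that fit. Immediate early genes were lower after stiff conditioning (33 of 37, median -0.23, adjusted p = 8.65e-04) and so was hypoxia and glycolysis (28 of 36, -0.14, adjusted p = 0.0153). Ribosomal proteins (64 of 65, 0.09, adjusted p = 8.65e-04), S phase (28 of 34, 0.10, adjusted p = 0.0153) and oxidative phosphorylation (35 of 40, 0.07, adjusted p = 0.0352) were higher. With an estimated correlation these 5 lists had an adjusted p of 0.891. Passing only with the block, and not with an estimated correlation, were the interferon (median -0.28, adjusted p = 0.0579 without and 1.33e-05 with the block), differentiation (-0.17, 0.156 and 0.00345), basal (-0.09, 0.183 and 0.00405), junction (-0.08, 0.506 and 0.0461) and NRF2 (0.12, 0.0874 and 0.00345) lists, with adjusted p of 0.728 and 0.808 under the block and an estimated correlation. Without soft-to-soft replicates 1 and 2 the hypoxia (adjusted p = 0.0523) and junction (0.0536) calls were lost with the block, and the junction call also with the correction for length and GC content (0.0522). C6orf15 stood at 2.00, L1CAM at 0.95, GRK7 at 1.97, S100A4 at 0.54, ABHD17C at -0.28, LINC00239 at -2.22, ZMYM1 at -0.42 and CSF2 at 0.83, none called.

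Between the learned conditions edgeR, DESeq2 and voom called 0 genes without the block, with 215 at an unadjusted p under 0.05 in edgeR. With the block edgeR and voom called 1 and DESeq2 176 (83 up and 93 down). THBD was called in 1 of 12 fits that left out a library, with adjusted p from 0.0423 to 0.684 and log2 fold changes from -0.50 to -0.44, and the count of calls in these fits lay between 0 and 3. Grouping the conditions by LPA exposure, or as stiff-to-soft with LPA-to-FAKi, gave 0 calls in edgeR with and without the block and 0 in voom, with 196 and 652 genes at an unadjusted p under 0.05 without the block and 679 and 2531 with it. Of the LPA receptors, LPAR1 and LPAR2 had condition means of at least 18.3 and 15.4 CPM, LPAR3 9.72 to 11.4 CPM, LPAR5 2.70 to 3.68 CPM and LPAR6 4.82 to 7.84 CPM, and none was called in any comparison. LPAR4 had too few counts to test.

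**Figure D4:**
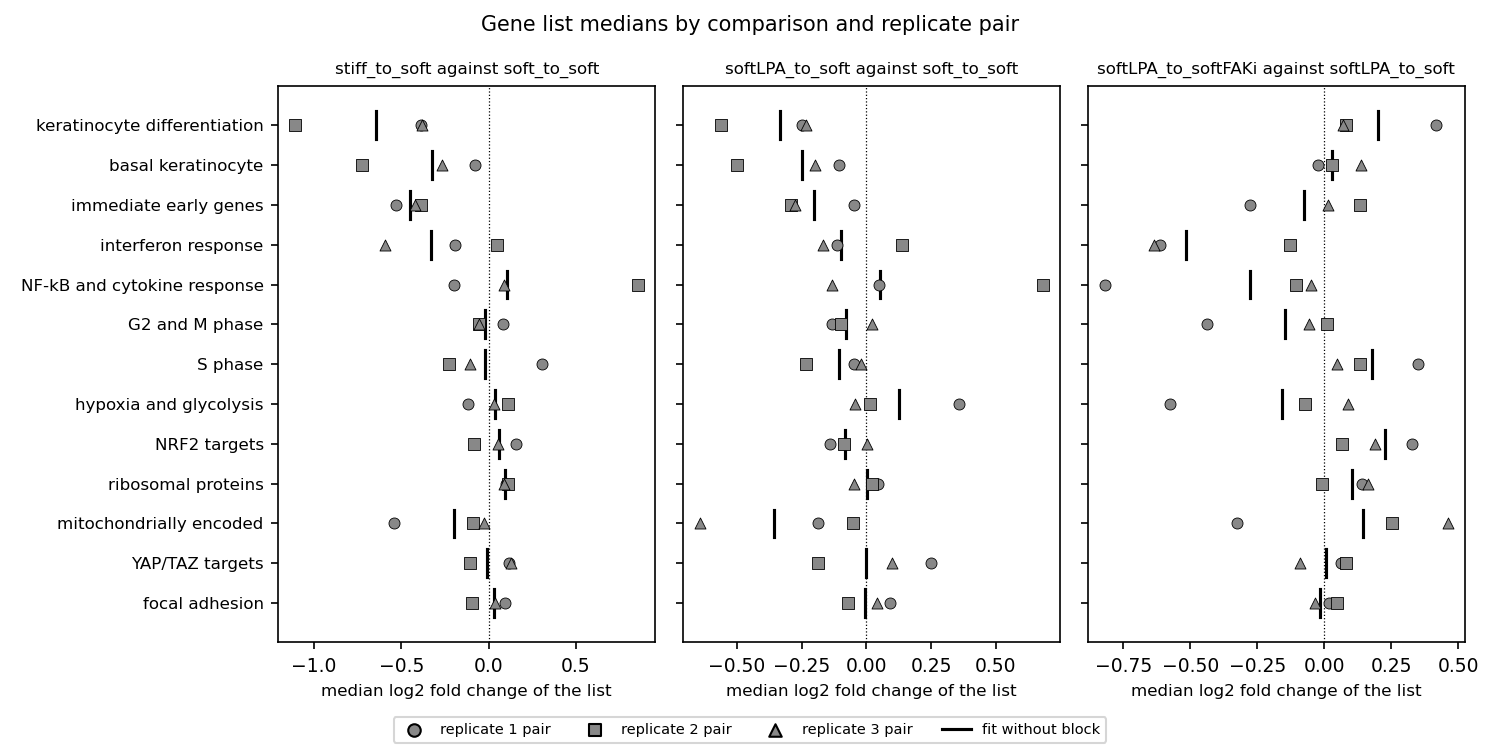
Median log2 fold change of 13 gene lists (y axis) in 3 comparisons, with markers for each replicate pair and bars for the fit without the block (x axis). Immediate early genes lie at -0.53, -0.39 and -0.42 in the pairs of stiff-to-soft against soft-to-soft, and the interferon list at -0.61, -0.13 and -0.64 in those of LPA-to-FAKi against LPA-to-soft.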

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

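The tests of transcript length and GC content, of left-out libraries on the interferon list, of the other counting and of other splits of the libraries were chosen after the results were seen.

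Among 114 sets of 6 libraries of a class, 5 held a library far from the other 5, where chance gives 5.7. The total count of LPA-to-soft replicate 3 was 121.1 M (121070917 counts), against 101.2 to 107.1 M in the other learned libraries. Mean log2 CPM of the hypoxia and glycolysis list was 6.71 in LPA-to-soft replicate 1, against 5.87 to 6.12. The log2 CPM of ALPK3 was 2.66 in soft-to-soft replicate 2, against 3.31 to 3.68. AREG stood at 2.17 in LPA-to-FAKi replicate 1, against 1.33 to 1.64. BIRC3 stood at 7.34 in stiff-to-soft replicate 1, against 7.71 to 7.91.

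The effects of stiff and LPA conditioning differed by a test of the difference for THBD with the replicate block (-0.46), a call made in 1 of 12 fits with a library left out. Without the block the difference passed for the lists of immediate early genes (-0.231), S phase (0.096), hypoxia and glycolysis (-0.137), ribosomal proteins (0.088) and oxidative phosphorylation (0.068), each with an adjusted p = 0.891 with an estimated correlation.

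The calls with the replicate block against soft-to-soft rest on controls of which 2 had low counts of another kind. If that other counting had made the calls, genes chosen from replicates 1 and 2 would keep their direction in the replicate 3 pair, counted alike, about as often as not. Of 89 genes chosen so in stiff-to-soft, 88 kept it (98.9%, median 0.60 in that direction), and of 87 in LPA-to-FAKi, 82 did (94.3%, median 0.43), which argues against the other counting as the whole cause. With replicate 2 held out instead, 71.3% of 87 LPA-to-FAKi genes kept their direction. A part that comes from the counting in the size of single fold changes stays open, as does a biological effect of the conditioning, which may set these genes apart.

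LPA-to-FAKi and LPA-to-soft differed by small amounts in many genes, with 3439 at an unadjusted p under 0.05 in the fit with the block and 0 called. The fold changes followed transcript length, with Spearman correlations across 11065 genes (which are not independent replicates) of -0.328 with length and 0.382 with GC content, and -0.238, -0.258 and -0.358 with length within the 3 pairs. Length also went with LPA-to-soft against soft-to-soft (0.372), and hardly with stiff-to-soft against soft-to-soft (0.003). After a correction for length and GC content 2789 genes stood at an unadjusted p under 0.05, against 772 from chance, of which 2106 were among the 3439 and kept their direction, which argues against these trends as the whole cause. RNA quality or fragment size in the LPA-to-soft libraries could give a length trend and was not measured, and a biological difference in long transcripts stays open.

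Interferon response genes were lower in LPA-to-FAKi than in LPA-to-soft, with a median of -0.47 in the fit with the block. After the correction for length and GC content the median was -0.43, and with any of the 12 libraries left out it lay between -0.66 (without LPA-to-FAKi replicate 2) and -0.37 (without LPA-to-FAKi replicate 3), so neither these trends nor 1 library accounts for the whole shift. The pair medians of -0.61, -0.13 and -0.64 differed more than this. The interferon level itself moved with replicate number, at 7.08 (mean log2 CPM) in soft-to-soft replicate 3 and 5.58 in replicate 2. An effect of FAK inhibition on interferon signalling is a hypothesis that these data leave open, and it may depend on that level.

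Other splits of the same libraries were counted for each comparison. For the classes without the block, 100 of 462 splits were drawn, and all 100 gave at least the real count of 0 calls, as any split must, so this count says nothing on chance. The highest other split called 2280 genes, and it put 4 libraries of replicate 1, 2 of replicate 2 and 0 of replicate 3 on 1 side. Such a count points to a structure of the samples that follows replicate number and not the classes. With the block, 100 of the 108 splits that take 2 libraries of each replicate number into each class were drawn. Of these, 2 gave at least the real count of 1, and the highest other also gave 1, so 1 call was reached by 1 other split of the same kind. Without the block the 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real count was 0 and the highest other 0 in each of the 5 comparisons, with 10 splits as large in each. With the block the 4 splits that keep the pairs are too few as well. The real counts were 90 for stiff-to-soft and 87 for LPA-to-FAKi against soft-to-soft and 1 between the learned conditions, each with a highest other of 0 (1 split as large, the real one). They were 0 for LPA-to-soft against soft-to-soft and for LPA-to-FAKi against LPA-to-soft, with a highest other of 0 (4 splits as large).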

How the results depend on the processing

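The settings with the replicate block and another choice together, the halved counts, the correction for length and GC content and the fits without soft-to-soft replicates 1 and 2 were chosen after the data were seen. The paired fit, with replicate number as a block, raised the counts of calls from 0 to 1 for the classes and for the learned grouping among the 3 groupings, 90 for stiff-to-soft against soft-to-soft, 87 for LPA-to-FAKi against soft-to-soft and 1 between the learned conditions. It kept the 42 list calls made without it and raised their number to 58, of which 0 stayed with an estimated correlation. DESeq2 without the block gave 3 for stiff-to-soft and 3 for LPA-to-FAKi against soft-to-soft. Without the block the counts stayed at 0 in edgeR under RLE scaling, no filter, a higher filter, robust spread, adjusted p under 0.01, a fold change minimum, left-out conditions or libraries, and in voom. The cause was not tested for any change given here.

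In fits with the block, counts follow the order classes, stiff-to-soft against soft-to-soft, LPA-to-soft against soft-to-soft, LPA-to-FAKi against LPA-to-soft, LPA-to-FAKi against soft-to-soft and stiff-to-soft against LPA-to-soft. They were 1, 90, 0, 0, 87 and 1 in edgeR. DESeq2 gave 130, 506, 148, 1224, 712 and 176, and 16 reversed genes, which fits with 0 calls in LPA-to-soft could not give. Voom gave 1, 119, 0, 37, 176 and 1, RLE scaling 1, 101, 0, 0, 91 and 0, and no filter 1, 158, 0, 25, 206 and 1. At an adjusted p under 0.01 they were 0, 8, 0, 0, 0 and 0. Fits of only the 2 conditions compared, which have fewer samples, gave 1 (EGR3), 3 (BTG2, FN1 and MMP10), 0, 1 (IFI6) and 4 (IL17C, SPRR2A, ZBED6CL and ZNF750) after the classes, and the 4-condition contrast gave 7 for the classes. Without soft-to-soft replicates 1 and 2 they were 4 (FN1, LCE3E, MALL and TNS3), 0, 0, 202, 0 and 1 (IL17C), and with the correction for length and GC content 0, 91, 0, 0, 103 and 0. Genes in parentheses were chosen after their values were seen. With 1 library left out, the counts ranged from 0 to 4, 7 to 228, 0 to 0, 0 to 639, 0 to 307 and 0 to 3.

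Of 6235 values of 141 named genes under these settings, 5140 stayed uncalled in the same direction, 1088 were called in the same direction and 7 turned. The reference is the fit without the block, which called no gene. The 5140 are therefore no measure of how stable the calls with the block were. These 7 were uncalled values without the block. Without soft-to-soft replicates 1 and 2 they were SPRR2E (0.092) and TMPRSS11D (0.148) in stiff-to-soft, KRT4 (0.352) and KRT10 (0.008) in LPA-to-soft and KRT15 (0.005) in LPA-to-FAKi. Without soft-to-soft replicate 1 they were TMPRSS11D (0.006) in stiff-to-soft and KRT15 (0.071) in LPA-to-FAKi. TMPRSS11D stood at -2.46 without stiff-to-soft replicate 1, and KRT15 at -1.21 without LPA-to-FAKi replicate 1. With the block CSF2 in stiff-to-soft and FN1 in stiff-to-soft were called in 12 of 12 fits with a library left out, CSF2 in LPA-to-FAKi in 11 (adjusted p = 0.0536 without soft-to-soft replicate 3). The 42 list calls were all lost with an estimated correlation and with fry, both without the block, and kept with RLE scaling. Fry with the block passed for immediate early genes and differentiation in stiff-to-soft against soft-to-soft. It did not pass for basal genes there (adjusted p = 0.125) or for differentiation in the classes (adjusted p = 0.135). With the block 41 list calls were kept under halved counts, 41 under the correction for length and GC content and 33 without soft-to-soft replicates 1 and 2. Lost in this last setting were mitochondrially encoded genes for the classes, NF-kB in stiff-to-soft, basal, NF-kB and hypoxia in LPA-to-soft, basal, TGF-beta and G2 and M phase in LPA-to-FAKi against soft-to-soft, and hypoxia between the learned conditions. Separated genes numbered 21 with RLE scaling and 31 with no filter, and r between stiff and LPA effects was 0.496 with RLE scaling and 0.518 with the block. With 3 libraries per condition, few 1.5-fold changes can be found without the block.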

Other observations

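The tests in this part were chosen after the data were seen. Several genes of other lineages were expressed in these carcinoma cells. COL1A1, a fibrillar collagen, had a mean of 19.1 CPM, the endothelial cadherin CDH5 16.0 CPM and the lysosomal marker CD68 17.1 CPM (43.3 CPM in the highest library). Some other markers of the same cell types were near 0, with means of 0.0155 CPM for DCN, 0.00605 CPM for PTPRC and 0.00902 CPM for PECAM1. Others were expressed at a low level, such as COL1A2 at 1.74 CPM, CD14 at 3.21 CPM and VWF at 2.18 CPM. IGFBP3, a YAP target, was among the abundant transcripts at 4932 ± 341 CPM in stiff-to-soft and 3612 ± 609 CPM in soft-to-soft (SD, n = 3), and was not called with the block (adjusted p = 0.119). THBD, chosen after its values were seen, moved in opposite directions against soft-to-soft with the block. It fell by 0.48 in stiff-to-soft (adjusted p = 0.0054) and rose by 0.29 in LPA-to-FAKi (adjusted p = 0.0431), where it was at 112.1 ± 22.7 against 91.7 ± 18.3 CPM (SD, n = 3).

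In 21 genes all 6 learned libraries lay above or all below the 6 other libraries, and none of these was called. If all 12 libraries were exchangeable the number would be 33.4, but replicate numbers pair them. The genes named here were picked by this separation in the same libraries, so their fold changes are no separate support. The values are log2 fold changes of the fit without the block. Among the 15 above were the BMP regulator BMPER (1.39, SE 0.424), the small GTPase RASL10A (2.32, SE 0.669), the kinases JAK1 (0.18) and PRKD3 (0.20), and SVIL and ALPK3. Among the 6 below were the gluconeogenic enzyme FBP1 (-0.95, SE 0.314) and the adhesion ligand CD58 (-0.14).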
